A study of Mus musculus with 6 samples.

How the data were processed

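The data are gene-level RNA-seq values of 6 libraries of monocytes sorted from subcutaneous B16.F10 melanoma tumours in mice, 3 from tumours of BAFF-overexpressing cells and 3 from tumours of control cells, taken 13 days after inoculation. Groups and replicate numbers come from the sample titles. A source label of the samples names the melanoma line where the series design names sorted monocytes, and the design was followed here. Libraries were made with the TruSeq RNA v2 kit, which does not mark strand, and sequenced on an Illumina HiSeq, per the labels' protocols. The submitters' processing notes name Partek, STAR (version 2.4.1d) and Bowtie2 (version 2.2.5) without their roles. The genome build, the annotation, the counting rule and any filter are not given in the sources used here, so no coordinates are printed.

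The authors deposited 1 table of 18341 genes in CPM, identified by its values: within a library, low values are mostly whole multiples of 1 step shared by all genes, as reads divided by a library total are. Between 80.17% and 85.35% of the low values lay within 0.02 of a whole multiple, so reads were not recovered gene by gene and no count model was used. The step gives the number of reads behind 1 CPM, and so the read total by which each library was divided; it was 4.72 to 27.6 reads per CPM. The listed genes held 39.8% to 66.1% of that total, so it included reads outside them. A control column whose name lacks a letter was matched to control tumour 2, the title it fits. Symbols were compared with GENCODE mouse release M21, and 18238 of the 18341 matched; the type of CT010467.1 was taken from there. No pair of libraries of 1 group was alike to within sampling noise, the smallest chi-square per degree of freedom being 8.18.

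The analysis was planned for counts, with a test for normalized values as the fallback. Because the table held CPM, the fallback became the test used: limma-trend (limma 3.58.1 in R 4.3.3) on log2(CPM + 1) of the deposited values with no rescaling, over the 12824 genes with a mean of 1 CPM or more, with Benjamini-Hochberg adjusted p under 0.05. The pseudocount of 1 understates fold changes of low genes. Errors of CPM are SD over 3 libraries and errors of fold changes are SE. The estimated prior degrees of freedom were infinite, so genes of 1 level shared nearly the same SE. Median-of-ratios size factors (RLE), which were set out in advance and computed on the tested genes, have their values beside the deposited ones.

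A set of 33 gene lists with 657 entries was fixed before the data were examined, together with the groups, the tests, the naming rule and most of the other settings tried. The lists cover BAFF pathway, immunosuppression, NF-kB, antigen presentation, interferon, cytokine, activation, metabolic, stress and cell cycle genes, and markers of cell types that a monocyte sort from a melanoma could hold. Of the entries 48 were not found and are not analysed here. The keratinocyte and mitochondrial lists had fewer than the 3 tested members required, which left 31 lists. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 31, and again with an estimated correlation and with fry, which asks whether a list by itself moves on balance in 1 direction. The naming rule took the BAFF gene and its receptors, the 12 genes per direction with the smallest adjusted p among those without overlap between groups and with a mean of 5 CPM or more in a group, and for each list the 4 members with the smallest p, plus the most abundant member of marker lists.

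Set out in advance were RLE and upper-quartile factors, voom weights on estimated reads, no filter, a filter at a mean of 5 CPM, a pseudocount of 0.1, a minimum absolute log2 fold change of 1, the replicate number as a block, and leaving out each library. Chosen after seeing the data were trimmed-mean factors, and RLE together with the block, a term for depth, only the 4 shallow libraries, each library left out, or the other list tests. The method was tested on simulated reads for the 12824 genes of the BAFF tumour against control tumour comparison at the real depths and library scales. All simulated genes shared 1 assumed dispersion, and equal numbers were made to rise and fall. The rates need not hold for the real data, where neither is given. The deposited scale recovered 19% of genes changed by 1 and 95% of those changed by 2 on the log2 scale with 0 false calls, and RLE recovered 73% and 100% with 5 false calls. With library scales made equal instead, the deposited scale and RLE each recovered 75% and 100% with 10 false calls. In 50 simulated draws of lists of 30 genes, camera gave an unadjusted p under 0.05 for 100% of changed and 2% of unchanged lists. Calls of the real lists used adjusted p. The simulated genes varied independently, which real genes do not, so the 2% does not hold for real lists.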

Results

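RNA sequencing had been done on monocytes sorted from subcutaneous B16.F10 tumours of C57BL/6 mice, 13 days after the cells were injected. B16.F10 is a pigmented mouse melanoma line. The injected cells either overexpressed BAFF, the B cell activating factor encoded by Tnfsf13b, or were control cells, and each group had 3 libraries. The comparison asks how BAFF made in the tumour changes the transcripts of tumour monocytes, in particular those of an immunosuppressive programme. The labels do not say whether the 3 libraries of a group came from separate mice, so the p-values refer only to these samples. On the deposited scale limma pooled the spread between libraries over genes of similar level, because the estimated prior degrees of freedom were infinite. An SE or p-value of a gene on that scale therefore does not reflect that gene's own spread, which can be wider.

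The deposited table listed 18341 genes in CPM, read counts scaled to a common library total. Depth was estimated from the step between low values. In BAFF tumour libraries 1, 2 and 3, 1 CPM stood for 9.65, 27.6 and 10.1 reads, and in control tumour libraries 1, 2 and 3 for 27.3, 7.12 and 4.72 reads. The floor of 3 reads lay between 0.109 and 0.635 CPM, for counting error only. The listed genes held 62.5%, 66.1% and 61.1% of the CPM total in the BAFF tumour libraries and 65.6%, 50.2% and 39.8% in the control libraries. In control tumours 2 and 3 the ribosomal RNA gene CT010467.1 stood at 27017 and 43052 CPM, against 299 CPM in control tumour 1 and 693 to 5880 CPM in the BAFF tumour libraries. The exact permutation test, whose smallest possible p in this design is 0.1, detected no difference between groups in summed CPM (two-sided p = 0.3) or in CT010467.1 (p = 0.4). Limma did call CT010467.1 lower in BAFF tumour libraries on the deposited scale (log2 fold change -1.38 ± 0.33, SE; adjusted p = 0.001697), though the groups overlapped. That call was lost without BAFF tumour 2, control tumour 2 or control tumour 3 (adjusted p at most 0.958), after size factors (adjusted p = 0.538), with upper-quartile factors and with no filter.

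**Figure D1:**
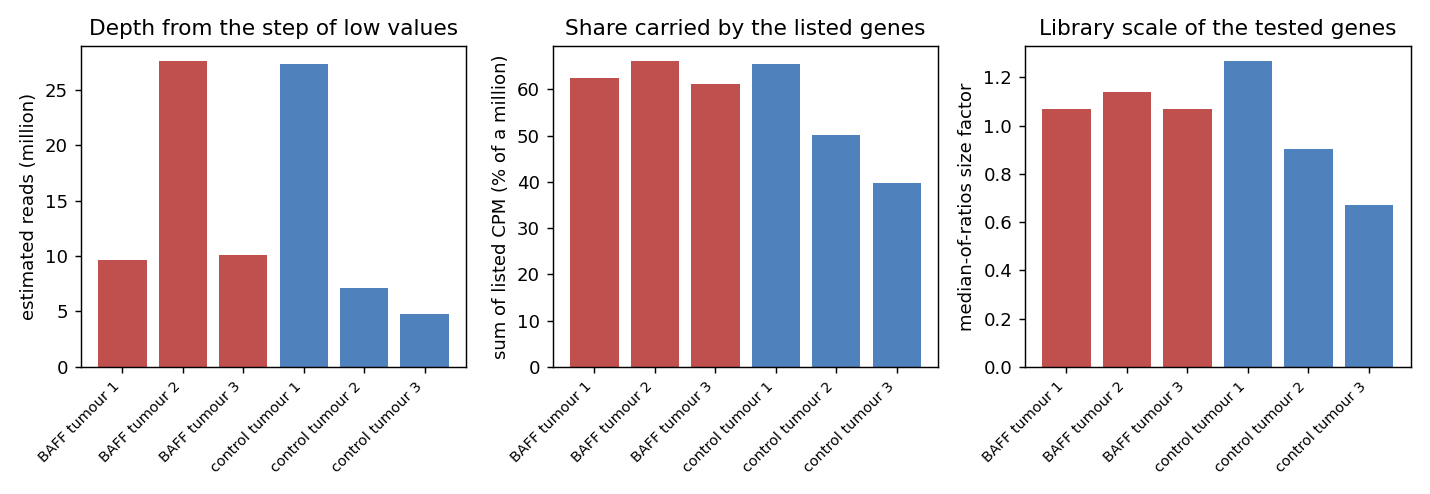
Estimated read total, share of the CPM total held by the listed genes, and median-of-ratios size factor are drawn as 1 bar per library, red for BAFF tumour and blue for control tumour. The size factors of the control libraries (1.27, 0.904 and 0.670) spread more widely than those of the BAFF tumour libraries (1.07, 1.14 and 1.07).

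The BAFF gene itself was scarce in the sorted cells, and no difference was detected. Tnfsf13b stood at 1.39 ± 0.54 CPM (SD, n = 3) in BAFF tumour libraries and 1.42 ± 0.50 CPM in controls, a log2 fold change of -0.02 ± 0.30 (SE; limma adjusted p = 0.976). Of its receptors, Tnfrsf13b (TACI) was present at 19.6 ± 2.9 and 16.4 ± 5.02 CPM, log2 fold change 0.27 ± 0.32 (adjusted p = 0.679). Tnfrsf13c, the BAFF receptor proper, averaged 0.258 and 0.0732 CPM and was below the level at which genes were tested. The receptor gene Tnfrsf17 was not analysed here. Tnfsf13, the related ligand APRIL, stood at 16.3 ± 2.9 and 13.1 ± 3.6 CPM (adjusted p = 0.639). None of the 3 tested genes of this list passed in limma, and the list was not called (adjusted p = 0.945).

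Lyve1, Fcna, Folr2 and the pigment genes Dct and Pmel were among the 12 lower genes taken by the naming rule. Lyve1, a hyaluronan receptor of lymphatic endothelium and a subset of tissue macrophages, fell from 42.9 ± 23.8 to 1.82 ± 0.75 CPM, a log2 fold change of -3.87 ± 0.31 (adjusted p = 1.30e-30). Fcna, which encodes the macrophage lectin ficolin A, fell from 22.8 ± 16.1 to 1.82 ± 0.15 CPM (log2 -2.88 ± 0.31), and Folr2, the folate receptor beta of macrophages, from 61.9 ± 27.2 to 13.5 ± 2.3 CPM (log2 -2.04 ± 0.32). The pigment gene Dct fell from 202 ± 54.4 to 47.8 ± 14.8 CPM (log2 -2.07 ± 0.32) and Pmel from 99.9 ± 44.7 to 24.03 ± 10.7 CPM (log2 -2.04 ± 0.32). The matricellular protein gene Sparcl1 (log2 -2.51), the Rap exchange factor gene Rapgef4 (-2.27), the adhesion genes Nrcam (-2.14) and Ptprm (-2.08), the kinase anchor gene Akap2 (-2.09), the actin regulator gene Nckap1 (-2.02) and the non-coding Snhg7os (-2.08) completed the 12, each with an adjusted p of at most 1.62e-07. Snhg7os is annotated opposite to Snhg7 and Akap2 overlaps a neighbouring gene, so without strand their reads are uncertain.

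Among the genes that rose, Htr7, a serotonin receptor gene, increased from 4.19 ± 0.67 to 17.3 ± 1.3 CPM (log2 fold change 1.82 ± 0.31, adjusted p = 3.06e-06), and Nrg1, which encodes an ErbB ligand, from 3.83 ± 2.6 to 14.03 ± 3.7 CPM (1.81 ± 0.31). Chil3, the chitinase-like protein Ym1 of recruited monocytes, rose from 98.99 ± 36.2 to 298 ± 56.8 CPM (1.62 ± 0.32), and Slc7a11, the cystine and glutamate exchanger, from 37.4 ± 17.6 to 117 ± 29.5 CPM (1.69 ± 0.32). Arg2, mitochondrial arginase, rose from 7.18 ± 4.6 to 21.1 ± 3.8 CPM (1.60 ± 0.32), and Sphk1, which makes sphingosine 1-phosphate, from 5.54 ± 1.8 to 19.8 ± 0.58 CPM (1.71 ± 0.31). Dmkn (log2 1.67), the transcription factor gene Spic (1.58), the glycosyltransferase gene B3gnt5 (1.60), the decoy interleukin 1 receptor gene Il1r2 (1.55), Ifitm1 (1.53) and the predicted gene Gm10718 (1.53) also rose, each with an adjusted p of at most 0.000188. Gm10718 belongs to a set of near-identical predicted genes, so its value is uncertain. Of these 24 genes, 23 passed in all 6 fits that left out 1 library, and Il1r2 missed without BAFF tumour 1 (adjusted p = 0.117). After size factors each of the 24 passed, with log2 fold changes from -4.07 for Lyve1 (limma adjusted p = 4.31e-06) to 1.65 for Nrg1.

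**Figure D2:**
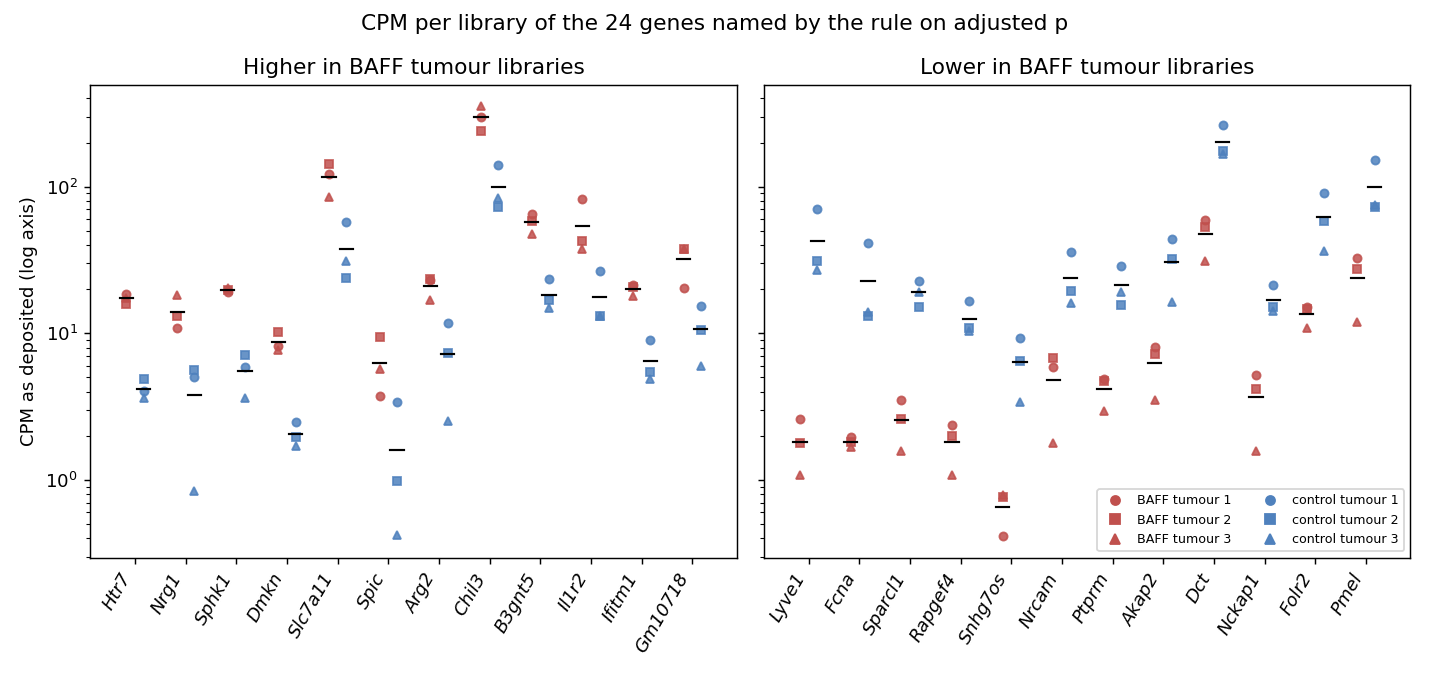
CPM as deposited (log axis) of the 12 higher and 12 lower genes taken by the naming rule, with 1 symbol per library, red for BAFF tumour and blue for control tumour, and a bar at each group's mean. The groups do not overlap for these genes, which the rule required, and the means of Lyve1 are 1.82 and 42.9 CPM.

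In all, 681 of the 12824 genes tested changed (limma-trend, adjusted p under 0.05), of which 232 were higher and 449 lower in BAFF tumour libraries, and 2053 had an unadjusted p under 0.05. The median of all tested genes was 0.23 higher in BAFF tumour libraries on the log2 scale for deposited values, a shift that the fold changes given here include. After median-of-ratios size factors (RLE) 2192 genes passed, 921 higher and 1271 lower, and 647 of the 681 passed in the same direction. Over all tested genes, the groups did not overlap in 35.2% after RLE, where chance leaves 10%. Without control tumour 1 the deposited-scale count became 5192 (4615 higher) and without control tumour 3 it became 1171. In the fit without control tumour 1 the median of all tested genes was 0.435 higher on the log2 scale. The same fit with RLE called 1834 (789 higher), so the 5192 include a shift of library scale. Leaving out BAFF tumour 1, 2 or 3 or control tumour 2 gave 258, 218, 167 or 315, and a filter at a mean of 5 CPM gave 316.

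Of 31 gene lists tested against all other genes, 16 were called, 10 higher and 6 lower (camera with a preset correlation of 0.01, adjusted p under 0.05). Camera with a correlation estimated for each list called 0, with 2 at an unadjusted p under 0.05, while fry called 0, with 4 at an unadjusted p under 0.05. After RLE fry called 10 of the 16, and not the hypoxia, cholesterol, neutrophil, B and plasma cell, fibroblast, or red cell and platelet lists. Splits of the 6 libraries that mixed the groups called 9 to 16 lists in camera at the preset correlation. Members named below only for a change after RLE were chosen after their values were seen. Calls of single genes near the threshold depended on the libraries used, and so did some far from it. Igha, for example, had a limma adjusted p of 3.06e-06 with all 6 libraries and 0.453 without BAFF tumour 2. Of the 83 called genes named here and in the closing section, 32 passed in all 6 fits that left out 1 library on the deposited scale. Calls lost without 1 library, here and below, are those of that scale. Over all tested genes, 110 passed in 1 direction in the full and every such fit on the deposited scale, and 1134 after RLE.

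Genes of myeloid immunosuppression moved up as a list (camera adjusted p = 1.34e-06; adjusted p = 0.887 with an estimated correlation). Of 26 tested members 8 rose, 0 fell and 18 did not pass, and 13 rose adjusted over the list alone. Neutrophil markers, which share S100a8 and S100a9 with this list, and Ly6C-high monocyte markers were called higher in the same libraries (camera adjusted p = 6.72e-06 and 6.36e-05; adjusted p = 0.887 for each with an estimated correlation). The list therefore does not separate a programme from a change in the mix of sorted cells. Besides Arg2, the members that rose were Nt5e, the ectoenzyme CD73 that makes adenosine (6.901 ± 4.8 to 19.3 ± 10.5 CPM, log2 1.44 ± 0.31, adjusted p = 0.000483) and Havcr2, the checkpoint receptor TIM-3 (42.6 ± 15.3 to 93.1 ± 13.6 CPM, 1.16 ± 0.32, adjusted p = 0.0101), with S100a8, S100a9 and Vegfa. The interleukin 1 receptor antagonist gene Il1rn (1.11 ± 0.32) and the PD-L2 gene Pdcd1lg2 (0.96 ± 0.32) rose too. Arg1, arginase 1, did not pass at 885 ± 185 and 800.1 ± 363 CPM (log2 0.23, and -0.03 after RLE). Arg1, Il1rn and Pdcd1lg2 are outside the naming rule and were chosen after their values were seen. After RLE 7 members passed as higher and Trem2 passed as lower, and Nt5e, S100a8, S100a9 and Pdcd1lg2 no longer passed (adjusted p = 0.0536, 0.176, 0.3099 and 0.142). The call of Nt5e was lost without BAFF tumour 1 or control tumour 2 (at most adjusted p = 0.306). The calls of Havcr2, Il1rn and Vegfa were lost without BAFF tumour 1, 2 or 3 or control tumour 2 (at most 0.252, 0.376 and 0.545). Those of S100a8 and S100a9 were lost without BAFF tumour 1 or 2 or control tumour 2 (at most 0.691 and 0.854), and that of Pdcd1lg2 without BAFF tumour 1, 2 or 3 or control tumour 3 (at most 0.514).

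Markers of Ly6C-high monocytes, the inflammatory blood monocytes that enter tumours, were called higher (camera adjusted p = 6.36e-05; adjusted p = 0.887 with an estimated correlation). Neutrophil markers and dissociation and early response genes were called higher in the same libraries (camera adjusted p = 6.72e-06 and 0.00114; adjusted p = 0.887 for each with an estimated correlation). Chil3, Hp (haptoglobin, 31.6 ± 8.7 to 68.3 ± 17.4 CPM, log2 1.09 ± 0.32), Clec4e (Mincle, 1.05 ± 0.32) and Vcan (versican, 0.97 ± 0.32) rose among 12 tested members, 0 fell, 8 rose adjusted over the list alone, and 8 passed as higher after RLE. Without BAFF tumour 1, 2 or 3 or control tumour 2 the calls of Hp, Clec4e and Vcan were lost (adjusted p at most 0.433, 0.517 and 0.384). F13a1, the most abundant tested member, stood at 838 ± 153 and 829.9 ± 369 CPM (log2 0.09, and -0.17 after RLE). Ly6C-low monocyte markers were not called (adjusted p = 0.2795) and 0 of 10 passed in limma, with Ace passing as higher and Cx3cr1 as lower after RLE and Cebpb at 148 ± 19.03 and 80.2 ± 4.4 CPM (adjusted p = 0.0944).

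The list of tumour macrophage markers was called lower (camera adjusted p = 0.00664; adjusted p = 0.887 with an estimated correlation), and not without control tumour 1 (0.0773). On the deposited scale 0 of its 16 tested members passed in limma. The complement gene C1qa stood at 280.1 ± 27.6 CPM in BAFF tumour libraries and 499 ± 174 CPM in controls (log2 -0.78 ± 0.32, adjusted p = 0.167), and Selenop at 382 ± 24.9 and 739 ± 506 CPM (-0.75 ± 0.32, adjusted p = 0.192). After RLE 8 members passed as lower, among them C1qa (-1.03 ± 0.11), Selenop (-1.001 ± 0.20), Vcam1 (-0.91 ± 0.21) and Mrc1 (-0.50 ± 0.12). Of the other 8 members, 7 did not pass and 1 passed as higher.

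Alternative activation genes moved both ways. Chil3, Ccl24, Cd209a and Tgm2 rose, Folr2, Retnla and Fcrls fell, and 14 of 21 did not pass. After RLE 3 passed as higher, without Ccl24, and 5 as lower, with Stab1 (-0.88 ± 0.10, adjusted p = 0.000209) and Mrc1 (adjusted p = 0.0145) added. Retnla, the secreted protein RELMalpha, fell from 17.6 ± 7.4 to 5.18 ± 1.2 CPM (log2 -1.54 ± 0.31, adjusted p = 0.000154) and missed without control tumour 2 (adjusted p = 0.06395). Fcrls fell from 36.7 ± 18.2 to 13.8 ± 4.03 CPM (-1.28 ± 0.32) and missed without BAFF tumour 3 (adjusted p = 0.264). Tgm2, transglutaminase 2, chosen after its values were seen, rose from 447 ± 133 to 886 ± 19.3 CPM (1.03 ± 0.32) and missed without BAFF tumour 1, 2 or 3 or control tumour 2 (at most 0.309). Cd209a missed without BAFF tumour 2 or 3 or control tumour 2 (at most 0.339). Ccl24, at 107 ± 28.1 against 70.5 ± 76.9 CPM, missed without any of the BAFF tumour libraries 1, 2 and 3 (at most 0.379) and after RLE (adjusted p = 0.331). The list was not called (adjusted p = 0.874), and camera placed it below other genes while its median log2 fold change was 0.27.

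Complement, phagocytosis and lysosome genes were not called (adjusted p = 0.874; median 0.21 against a downward camera direction), and 28 of 30 did not pass. After RLE Itgax, C3 and Itgb2 passed as higher and Gas6, C1qa, C1qb and C1qc as lower. Gas6, a ligand of the TAM receptors that bind dying cells, fell from 77.8 ± 32.1 to 25.4 ± 3.5 CPM (log2 -1.51 ± 0.32, adjusted p = 0.000252). Itgax (CD11c) rose from 58.2 ± 10.6 to 120.1 ± 18.7 CPM (1.04 ± 0.32, adjusted p = 0.0284), a call lost without BAFF tumour 1, 2 or 3 or control tumour 2 (at most 0.4201).

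Cell cycle genes fell together. Of 35 tested members 22 fell, 0 rose and 13 did not pass, and 30 fell adjusted over the list alone and 32 after RLE (camera adjusted p = 3.49e-37; adjusted p = 0.702 with an estimated correlation). Cenpf, a kinetochore protein gene, fell from 20.9 ± 5.2 to 6.53 ± 1.9 CPM (log2 -1.55 ± 0.32, adjusted p = 0.000139), Cenpe from 18.2 ± 5.96 to 5.596 ± 1.1 CPM (-1.50 ± 0.31), Aurkb, a mitotic kinase gene, from 9.58 ± 2.5 to 2.71 ± 0.58 CPM (-1.49 ± 0.31) and Ccna2, cyclin A2, from 19.1 ± 7.9 to 5.92 ± 1.2 CPM (-1.48 ± 0.31). The median over the list was -1.07, and -1.28 after RLE, in libraries where melanoma markers fell as well. Cenpf missed without BAFF tumour 3 (adjusted p = 0.0526).

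Melanoma cell markers fell in the same libraries. Of 13 tested members 11 fell and 0 rose, also adjusted over the list alone, with a median log2 fold change of -1.57 (-1.78 after RLE). Camera called the list (adjusted p = 6.73e-31; adjusted p = 0.564 with an estimated correlation). Tyrp1, like Dct and Pmel, fell from 121 ± 36.7 to 33.5 ± 11.8 CPM (-1.85 ± 0.32, adjusted p = 3.17e-06) and Mc1r, the melanocortin receptor gene, from 8.96 ± 2.6 to 1.65 ± 0.52 CPM (-1.89 ± 0.31, adjusted p = 5.52e-07). Mitf, a melanocyte transcription factor gene that myeloid cells also transcribe, did not pass at 70.1 ± 8.3 and 80.9 ± 28.3 CPM (-0.16, adjusted p = 0.811) and was chosen after its values were seen. After RLE 12 members passed as lower, Mitf among them (adjusted p = 0.0305).

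Neutrophil markers were called higher (camera adjusted p = 6.72e-06; adjusted p = 0.887 with an estimated correlation). Il1r2, Lcn2, S100a8, S100a9 and Cxcr2 rose, and 4 of 9 did not pass, among them Csf3r at 86.3 ± 15.9 and 53.9 ± 24.4 CPM. S100a8 stood at 16.3 ± 10.1 against 7.83 ± 7.4 CPM (log2 1.11 ± 0.31), S100a9 at 31.2 ± 20.01 against 16.05 ± 12.9 CPM (1.07 ± 0.32) and Lcn2, lipocalin 2, at 4.41 ± 4.9 against 0.979 ± 1.2 CPM (1.23 ± 0.30). The groups overlapped for S100a8, S100a9 and Lcn2. They passed neither after RLE nor without BAFF tumour 1 or control tumour 2 (adjusted p at most 0.691, 0.854 and 0.761). S100a8 and S100a9 also missed without BAFF tumour 2, and Cxcr2 missed without BAFF tumour 1, 2 or 3 or control tumour 2 (at most 0.557). For S100a8, S100a9 and Lcn2 the deepest library of each group, BAFF tumour 2 and control tumour 1, differed by -0.12, -0.02 and -0.18 on the log2 scale after RLE. Il1r2 missed without BAFF tumour 1 (adjusted p = 0.117). After RLE Il1r2, Csf3r and Retnlg passed as higher.

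The list of dendritic cell markers was not called (adjusted p = 0.2998; adjusted p = 0.922 with an estimated correlation) except with a filter at 5 CPM (0.0196), though Cd209a (7.63 ± 1.9 to 18.6 ± 6.4 CPM, log2 1.16 ± 0.32), Flt3 (1.03 ± 0.30) and Itgax rose among 13. Xcr1, at 0.795 against 1.95 CPM, did not pass. The call of Cd209a was lost without BAFF tumour 2 or 3 or control tumour 2, and those of Flt3 and Itgax also without BAFF tumour 1 (adjusted p at most 0.339, 0.296 and 0.4201). After RLE Cd209a, Flt3 and Itgax passed (limma adjusted p = 0.0208, 0.0114 and 0.0038). B and plasma cell markers were called lower (camera adjusted p = 0.00477; adjusted p = 0.887 with an estimated correlation), and not without control tumour 1 (0.0766), with upper-quartile (0.0618) or trimmed-mean factors (0.0517), with no filter (0.0519) or with RLE in the 4 shallow libraries (0.226). Jchain, the joining chain of secreted IgM and IgA, fell from 5.31 ± 3.3 to 2.12 ± 1.5 CPM and Igkc from 11.2 ± 6.5 to 4.91 ± 1.6 CPM among 4 tested members, while Ighm did not pass at 28.7 ± 7.8 and 34.5 ± 19.3 CPM. Jchain missed without BAFF tumour 2 or 3 (at most 0.792), and Igkc without BAFF tumour 1, 2 or 3 or control tumour 1 or 2 (at most 0.651). After RLE Jchain and Igkc passed as lower (limma adjusted p = 0.0298 and 0.00746).

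The list of fibroblast markers was called lower (camera adjusted p = 1.95e-05; adjusted p = 0.887 with an estimated correlation), and not without control tumour 1 (0.368) or with RLE in the 4 shallow libraries (0.894). In limma 0 of 14 passed, Col1a1 and Sparc passed as lower after RLE, and Col1a1 stood at 9.55 ± 2.9 and 24.7 ± 23.98 CPM (adjusted p = 0.0641). The list of red cell and platelet markers was called lower (camera adjusted p = 0.001404; adjusted p = 0.887 with an estimated correlation), and not without control tumour 1 (0.0799), with upper-quartile factors (0.0618) or with RLE in the 4 shallow libraries (0.209). In limma 0 of 6 passed, with the platelet factor gene Pf4 at 86.9 ± 32.1 and 117 ± 53.7 CPM and the haemoglobin gene Hba-a2, which has a near-identical copy, at 1.796 ± 0.69 and 4.18 ± 3.1 CPM. T and NK cell markers (adjusted p = 0.844, 0 of 16 passing) and endothelial markers (adjusted p = 0.9704, 0 of 6 passing) were not called in camera or limma. For endothelial markers the median (0.06) and the camera direction differed in sign, and after RLE Kdr and Pecam1 passed as higher and Eng as lower. Gzmb, granzyme B, stood at 7.17 ± 0.86 and 3.93 ± 3.2 CPM (adjusted p = 0.0516), and Kdr, a VEGF receptor gene, at 11.9 ± 1.9 and 6.08 ± 1.5 CPM (adjusted p = 0.0808). The list of mast cell, basophil and eosinophil markers was not called (adjusted p = 0.133; adjusted p = 0.887 with an estimated correlation) except without control tumour 2 (0.0338) or with no filter (0.0264). Of its 3 tested members Ccr3 rose from 2.803 ± 2.1 to 6.65 ± 1.9 CPM (log2 1.16 ± 0.31, adjusted p = 0.00636), and missed without BAFF tumour 2 or 3 or control tumour 3 (at most 0.266) and after RLE (0.0634). Keratinocyte markers were not tested as a list, and their member Sfn stood at 1.62 ± 0.25 and 0.779 ± 0.45 CPM (adjusted p = 0.3098).

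The co-stimulatory genes Cd80 and Cd86, which encode ligands of CD28, both rose. Cd80 went from 40.5 ± 13.1 to 85.2 ± 10.5 CPM (log2 1.09 ± 0.32, adjusted p = 0.0175) and Cd86 from 70.8 ± 25.6 to 143 ± 23.5 CPM (1.05 ± 0.32, adjusted p = 0.0264), and 10 of 12 in their list did not pass (list adjusted p = 0.136). Both calls were lost without BAFF tumour 1, 2 or 3 or control tumour 2 (at most 0.329 and 0.449). After RLE both genes passed (limma adjusted p = 0.000984 and 0.000538). The MHC class II presentation list was not called (adjusted p = 0.0854), but was called after RLE (camera adjusted p = 0.0499; after RLE, adjusted p = 0.5803 with an estimated correlation and 0.247 in fry). It was also called without BAFF tumour 1 or control tumour 3 (0.0277 and 0.0273). In limma 0 of 12 passed, H2-DMb1 passed as higher after RLE, and H2-Aa stood at 1562 ± 271 and 1139 ± 542 CPM (adjusted p = 0.419). MHC class I genes were not called (adjusted p = 0.219), with 0 of 15 passing and Tapbp at 279 ± 36.6 and 203 ± 61.5 CPM.

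Among inflammatory cytokines and chemokines, Cxcl2, which attracts neutrophils, rose from 524 ± 191 to 1038 ± 209 CPM (log2 1.02 ± 0.33, adjusted p = 0.0361), Ccl24 rose and Ccl8 fell from 174 ± 95.8 to 77.6 ± 17.4 CPM (-0.96 ± 0.32, adjusted p = 0.0499). The calls of Cxcl2 and Ccl8 were lost without BAFF tumour 1, 2 or 3 or control tumour 2 (at most 0.463 and 0.711). The call of Ccl24 was lost without BAFF tumour 1, 2 or 3 (at most 0.379). In that list 23 of 26 did not pass, and after RLE Cxcl2, Osm and Csf1 passed as higher and Ccl8 as lower. It was not called (adjusted p = 0.0536; adjusted p = 0.887 with an estimated correlation), but was called without BAFF tumour 3 or control tumour 1 (0.00465 and 0.0371), with voom (0.0316) and with no filter (0.0226). The NF-kB list was called higher (camera adjusted p = 0.000338; adjusted p = 0.887 with an estimated correlation), with Cxcl2 the single member of 31 that rose, and 0 adjusted over the list alone in limma. After RLE 12 passed, among them Nfkb1 (0.57 ± 0.12), Traf1 (0.66 ± 0.14) and Birc3 (0.65 ± 0.13). In the same libraries neutrophil markers, Ly6C-high monocyte markers and dissociation and early response genes were called higher (camera adjusted p = 6.72e-06, 6.36e-05 and 0.00114; adjusted p = 0.887 for each with an estimated correlation).

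In the interferon-gamma response list Jak2 rose from 73.4 ± 24.2 to 141 ± 7.9 CPM (log2 0.99 ± 0.32, adjusted p = 0.0425) and 26 of 27 did not pass, with Gbp2 at 540.5 ± 161 and 284 ± 87.2 CPM. After RLE Jak2, Gbp2 and Cd274 passed as higher and Irgm2 as lower. Jak2 missed in each fit without 1 library except that without control tumour 1 (at most 0.358). The list was not called (adjusted p = 0.816; adjusted p = 0.982 with an estimated correlation) except without BAFF tumour 1 (0.0186). In the type I interferon response list Siglec1, the sialoadhesin of macrophages, fell from 156 ± 59.8 to 60.6 ± 22.6 CPM (-1.32 ± 0.32, adjusted p = 0.00209), a call lost without BAFF tumour 1 or 2 or control tumour 2 (at most 0.186), and 29 of 30 did not pass. Ifit3 stood at 46.3 ± 4.96 and 72.3 ± 23.8 CPM. After RLE 4 passed as lower, Siglec1, Ifit3 (-0.83 ± 0.12, adjusted p = 0.000914), Ifi44 (-1.02 ± 0.26) and Ifit2 (-0.64 ± 0.19). That list was not called (adjusted p = 0.351, median 0.17 with a downward camera direction; adjusted p = 0.982 with an estimated correlation). It was called lower without control tumour 3 (0.0153), with a filter at 5 CPM (0.0422) and with RLE in the 4 shallow libraries (0.0147).

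The list of chemokine receptor and adhesion genes was called higher (camera adjusted p = 0.00172; adjusted p = 0.887 with an estimated correlation). Cxcr4 rose from 188 ± 76.9 to 399 ± 23.7 CPM (log2 1.16 ± 0.32, adjusted p = 0.0106), Csf2rb, the shared beta chain of the GM-CSF receptor, from 196 ± 56.1 to 399.9 ± 34.4 CPM (1.06 ± 0.32), Ccr1 from 253 ± 54.99 to 508 ± 85.2 CPM (1.01 ± 0.32) and Cxcr2 from 2.099 ± 1.4 to 4.91 ± 1.5 CPM (0.99 ± 0.31). In that list 17 of 21 did not pass, and 9 rose and 1 fell adjusted over the list alone. After RLE 8 passed as higher and 2 as lower, Cx3cr1 (-0.63 ± 0.18) and Cxcr3 (-0.79 ± 0.21). In the same libraries neutrophil markers, which share Cxcr2 and Csf3r with this list, Ly6C-high monocyte markers, and dissociation and early response genes were called higher (camera adjusted p = 6.72e-06, 6.36e-05 and 0.00114; adjusted p = 0.887 for each with an estimated correlation). Without BAFF tumour 1, 2 or 3 or control tumour 2 the calls of Cxcr4, Csf2rb, Ccr1 and Cxcr2 were lost (at most 0.186, 0.323, 0.4298 and 0.557). After RLE Cxcr4, Csf2rb and Ccr1 passed (limma adjusted p = 0.000376, 0.000321 and 0.00291), and Cxcr2 missed (0.0624).

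Cholesterol synthesis genes were called higher (camera adjusted p = 3.71e-05; adjusted p = 0.887 with an estimated correlation). Pmvk (log2 1.08 ± 0.32), Fdps (1.07 ± 0.32), Msmo1 (1.03 ± 0.32) and Cyp51 (0.98 ± 0.32), enzymes of sterol synthesis, rose among 22, 11 rose adjusted over the list alone, and 11 passed as higher after RLE. Hypoxia and glycolysis genes were called higher (camera adjusted p = 0.00198; adjusted p = 0.887 with an estimated correlation), with the glucose transporter gene Slc2a3 (1.14 ± 0.32), Vegfa (208 ± 42.1 to 413 ± 87.7 CPM, 0.99 ± 0.32) and Hif1a (185 ± 40.9 to 362 ± 29.98 CPM, 0.99 ± 0.32) rising among 29. Adjusted over the list alone, 8 rose, and after RLE 10 passed as higher and 2 as lower, Car9 (-0.86 ± 0.18) and P4ha2 (-0.78 ± 0.15). Without BAFF tumour 1, 2 or 3 or control tumour 2 the calls of these 7 genes were lost, with adjusted p at most 0.284 for Pmvk, 0.376 for Fdps, 0.315 for Msmo1, 0.424 for Cyp51, 0.2898 for Slc2a3, 0.545 for Vegfa and 0.402 for Hif1a. A filter at 5 CPM also ended the calls of Cyp51, Vegfa and Hif1a, and no filter those of Vegfa and Hif1a. The replicate block ended those of Fdps, Msmo1, Cyp51, Vegfa and Hif1a. The neutrophil, Ly6C-high and dissociation lists were called higher in the same libraries (camera adjusted p = 6.72e-06, 6.36e-05 and 0.00114; adjusted p = 0.887 for each with an estimated correlation).

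The unfolded protein response list (camera adjusted p = 0.00292; adjusted p = 0.887 with an estimated correlation) and the ribosomal protein list (camera adjusted p = 0.00259; adjusted p = 0.887 with an estimated correlation) were called higher. In limma 0 of 21 and 0 of 34 members passed, and 8 and 4 passed as higher after RLE, the 4 being Rps6, Rps23, Rpl13 and Rpl37. Besides the dissociation list, neutrophil and Ly6C-high markers were called higher in the same libraries (camera adjusted p = 6.72e-06 and 6.36e-05; adjusted p = 0.887 for each with an estimated correlation). Atf4, a stress response transcription factor gene, stood at 225 ± 13.97 and 135 ± 46.1 CPM (adjusted p = 0.147) and Rps6 at 113 ± 7.3 and 74.3 ± 33.1 CPM (adjusted p = 0.246). Oxidative phosphorylation genes were not called (adjusted p = 0.219), with 0 of 31 passing in limma and Cycs at 42.7 ± 8.8 and 28.5 ± 11.7 CPM. Dissociation and early response genes were called higher (camera adjusted p = 0.00114; adjusted p = 0.887 with an estimated correlation), with Ier3 (1.01 ± 0.32) and the near-identical heat shock genes Hspa1a and Hspa1b (1.05 ± 0.32 and 1.09 ± 0.32) rising among 21, and 7 passed as higher after RLE. Those 3 calls were lost without BAFF tumour 1, 2 or 3 or control tumour 2 (at most 0.385, 0.3605 and 0.292).

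Other settings ended further calls. A filter at 5 CPM ended those of Jak2, Ier3, Vcan, Ccr1, Igkc, Pdcd1lg2 and Ccl8. The replicate block ended those of Fdps, Msmo1, Cyp51, Vegfa, Hif1a, Cd86, Itgax, Ccr1, Ier3, Jak2, Vcan, Igkc, Pdcd1lg2 and Ccl8. With no filter Vcan, Ccr1, Igkc, Pdcd1lg2, Cxcl2 and Tgm2 missed, with a pseudocount of 0.1 Ccl8, and with voom Cxcr2. Upper-quartile factors, like RLE, ended the calls of Nt5e, S100a8, S100a9, Pdcd1lg2, Lcn2, Cxcr2, Ccl24 and Ccr3.

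**Figure D3:**
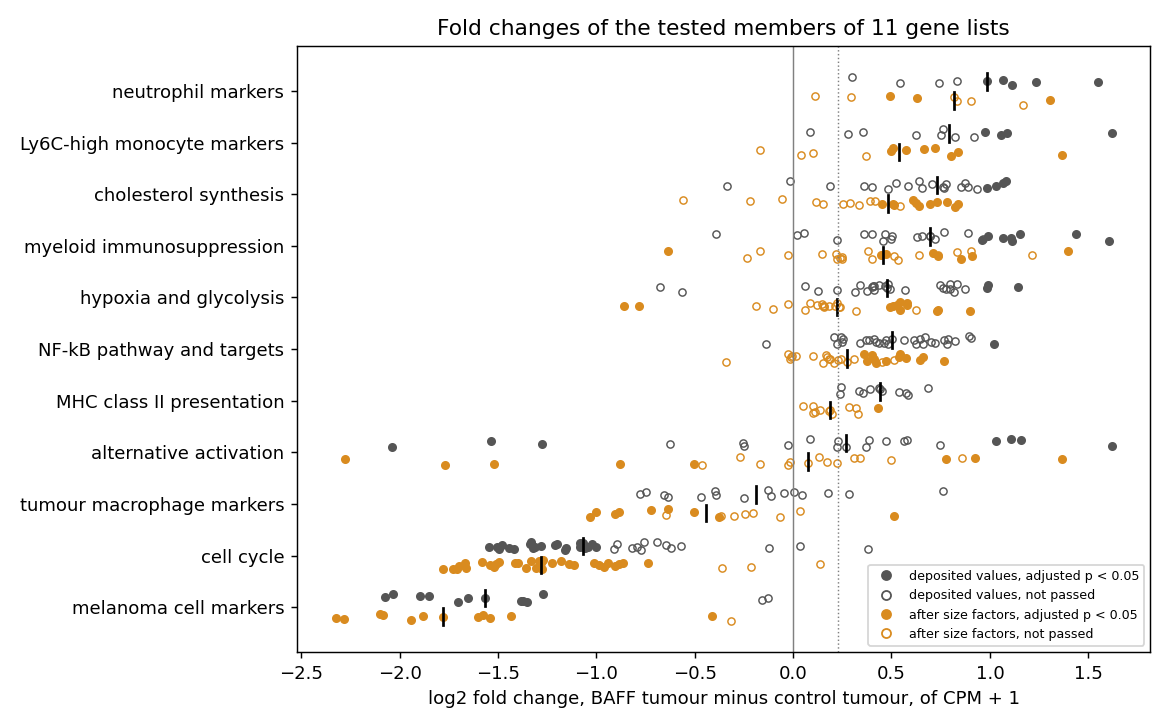
Log2 fold changes (BAFF tumour minus control tumour, of CPM + 1) of the tested members of 11 gene lists, grey for deposited values and orange after size factors, filled where the adjusted p was under 0.05, with a black bar at each list's median and a dotted line at 0.23, the median of all tested genes on the deposited scale. Melanoma and cell cycle genes have the lowest medians drawn, -1.57 and -1.07 for deposited values.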

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

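Trimmed-mean factors, and RLE combined with a block, a depth term, the 4 shallow libraries, each library left out, estimated correlation or fry, were chosen only after the result was seen. Named genes were tallied only in settings set out in advance. There 1410 values kept their direction and side of the threshold, 127 passed anew, 228 no longer passed and 15 reversed. Over the lists these numbers were 493, 18, 43 and 32, with trimmed-mean factors and RLE with the block, depth or shallow libraries included. None of the reversed genes and lists was called on the deposited scale. From 681 genes (232 higher, 449 lower), the counts became 2192 (921, 1271) with RLE, 2080 (686, 1394) with upper-quartile and 2169 (887, 1282) with trimmed-mean factors, 1940 (781, 1159) with RLE and the block, 2012 (847, 1165) with RLE and depth, 994 (391, 603) with RLE in the 4 shallow libraries, and 316 (142, 174) with a filter at 5 CPM, where 9096 genes were tested. Voom (888), no filter (877), pseudocount 0.1 (678), a log2 minimum of 1 (554) and the block (608) stayed within 1.5 times. Leaving out 1 library, with or without RLE, gave 167 to 5192 genes, 34 to 4615 higher and 128 to 1169 lower. With RLE alone the range was 1335 to 1834. Lists called went from 16 to 0 with an estimated correlation, 0 with fry (2 and 4 at an unadjusted p under 0.05), 0 with RLE and an estimated correlation (6 at an unadjusted p under 0.05) and 10 with RLE and fry, and were 13 to 18 elsewhere. Replicate numbers did not pair the libraries (correlations of deviations -0.0494, 0.0523 and -0.0387); under the block 14 named genes no longer passed and the list of inflammatory cytokines and chemokines was called (0.0447). The list MHC class II presentation was called, besides RLE alone, with RLE and the block (0.0402), depth (0.0499) or the shallow libraries (0.0455). In the simulated reads the deposited scale recovered 75% of genes changed by 1 (log2) at equal library scales and 19% at the real ones. Unequal library scales may thus hold down the deposited-scale count, within the limits of that simulation. Apart from this, the smaller sets of genes or libraries, and the shift of library scale without control tumour 1, the cause was not tested.

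Reversed log2 fold changes were those of Arg1 (RLE -0.028, upper-quartile -0.077), F13a1 (-0.17 and -0.22) and Tnfrsf13b (upper-quartile -0.012). Leaving out 1 library gave -0.099 to 0.56 for Arg1, -0.17 to 0.42 for F13a1, -0.39 to 0.25 for Ighm, -0.31 to 0.11 for Mitf and -0.21 to 0.13 for Tnfsf13b. List directions reversed, with these adjusted p values, for endothelial markers (upper-quartile 0.951, trimmed-mean 0.996, 5 CPM 0.741, fry 0.583), alternative activation (voom 0.975, no filter 0.804, fry 0.666), complement, phagocytosis and lysosome (voom 0.975, no filter 0.804, fry 0.685), T and NK cell markers (voom 0.830), interferon-gamma response (5 CPM 0.591), type I interferon response (fry 0.879), and, with RLE in the 4 shallow libraries, BAFF ligand and receptor genes (0.930) and oxidative phosphorylation (0.680). Without 1 library their adjusted p ran over 0.701 to 0.997 for endothelial markers, 0.399 to 0.916 for alternative activation, 0.5900 to 0.967 for complement, phagocytosis and lysosome, 0.375 to 0.975 for T and NK cell markers, 0.0186 to 0.853 for interferon-gamma response, 0.0153 to 0.9895 for type I interferon response and 0.5900 to 0.967 for BAFF ligand and receptor genes. The cause was not tested. A DESeq2 or edgeR test was not run, since the values are not counts. Depth limits genes under 0.635 CPM, the floor of 3 reads in control tumour 3.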

Other observations

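The gene families, the abundant genes and the tests of explanations below, except the counts over splits of the libraries, were chosen only after the result was seen. Many replication histone genes, which are transcribed in S phase, fell. Of 53 tested 29 fell and 0 rose in limma, and 42 passed as lower after RLE, among 12 families of symbols looked at. Cell cycle genes and melanoma markers fell in the same libraries (median log2 fold changes -1.07 and -1.57). Hist1h2bb fell from 19.4 ± 3.8 to 5.23 ± 0.41 CPM (log2 -1.69 ± 0.31) and Hist1h3b from 8.83 ± 2.4 to 2.08 ± 0.55 CPM (-1.66 ± 0.31); histone genes have near-identical copies, so single values are uncertain. Of 8 immunoglobulin genes 3 fell: Ighg2b, with 0, 0 and 0.0987 CPM in BAFF tumour libraries against 3.95, 1.97 and 4.45 CPM in controls, Igkc, and Igha, from 17.9 ± 6.9 to 6.04 ± 4.9 CPM, which missed without BAFF tumour 2 (adjusted p = 0.453). Igkc missed without BAFF tumour 1, 2 or 3 or control tumour 1 or 2 (at most 0.651).

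Among 297 genes with a mean of at least 300 CPM in either group, 25 rose and 1 fell, the ribosomal RNA gene CT010467.1, whose groups overlapped and which did not pass after RLE (adjusted p = 0.538). After RLE 89 passed as higher and 10 as lower. Thbs1, the gene of the secreted glycoprotein thrombospondin 1, rose from 3287 ± 598 to 7000.1 ± 1355 CPM (log2 1.09 ± 0.33, limma adjusted p = 0.0236), Tgfbi from 590.3 ± 119.5 to 1331 ± 101 CPM (1.19 ± 0.33), Plaur, the urokinase receptor gene, from 175 ± 21.8 to 384 ± 22.3 CPM (1.13 ± 0.32) and F10, coagulation factor X, from 156 ± 32.5 to 399 ± 72.3 CPM (1.35 ± 0.32). Clec7a, the beta-glucan receptor Dectin-1, rose from 532 ± 141 to 1302 ± 148 CPM (1.32 ± 0.33), and with Clec4n (1.43 ± 0.32), Clec4d (1.12 ± 0.32) and Clec4e 4 of 17 tested C-type lectin genes rose and 0 fell. These genes passed after RLE. On the deposited scale the calls of Thbs1, Tgfbi, Plaur, Clec7a, Clec4d and Clec4e were lost without BAFF tumour 1, 2 or 3 or control tumour 2 (adjusted p at most 0.387, 0.196, 0.237, 0.131, 0.419 and 0.517), that of F10 without BAFF tumour 1 or 2 (at most 0.114) and that of Clec4n without BAFF tumour 2 or control tumour 2 (at most 0.127). The call of Thbs1 was also lost with no filter.

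The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. On the deposited scale 1 of 10 splits, the real one, gave as many as 681 genes, and the highest other split gave 12. After RLE 1 of 10 gave 2192, and the highest other gave 0. For gene lists 2 of 10 splits gave 16 or more calls, the real one and that of BAFF tumours 1 and 3 with control tumour 3, which also gave 16; the splits that mixed the groups gave 9 to 16, so the number of lists called does not set the real grouping apart.

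Melanoma cell markers fell in the BAFF tumour libraries (list adjusted p = 0.564 with an estimated correlation), with Dct at 202 CPM in controls the most abundant of them, from a sort meant to hold monocytes. A library scale moves all genes alike, but the median of the 13 tested members minus that of all tested genes was -1.797 on the deposited log2 scale (SD of members 0.6232) and -1.79 after RLE, which argues against library scale as the whole cause. The SD of members, here and below, is not a spread between libraries, since members of a list move together. A smaller share of melanoma cells or their RNA in BAFF tumour sorts would lower markers taken to be absent from monocytes by 1 ratio. Only members with a mean of 5 CPM or more were used for this. Of these 9, 1 lay over 2 SE from their median of -2.10 after RLE without a pseudocount (range -2.70 to -1.74). A share 4.28-fold lower on that scale is 1 reading that these values allow, and they do not single it out. The SE of each member includes spread between libraries that members share (estimated correlation 0.795), which makes it hard for a member to lie apart. Mitf was left out of these 9 after a first look, because myeloid cells also transcribe it; with it 2 of 10 lay apart and the bound set for this explanation would not have been met. BAFF acting on the transcripts of melanoma cells would pass the same bound if it lowered these genes alike, and it stays open as untested.

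Cell cycle genes fell as well (list adjusted p = 0.702 with an estimated correlation), and their median minus that of all tested genes, -1.298 on the deposited scale (SD of members 0.4393) and -1.29 after RLE, argues against library scale as the whole cause. Whether melanoma cells bring all of the cell cycle transcripts cannot be told apart from a change in other cells. With the 9 melanoma genes used above, without Mitf, the log2 ratio of cell cycle to melanoma genes was higher in BAFF tumour libraries by 0.7807 (SE 0.3342). The groups were apart only narrowly, the lowest BAFF tumour value being -0.372 and the highest control value -0.454. With Mitf counted among the melanoma genes, though myeloid cells also transcribe it, the difference was 0.608 (SE 0.310) with overlap. Fewer dividing monocytes in BAFF tumours may also contribute, and this was not tested.

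The list of tumour macrophage markers was called lower and that of Ly6C-high monocyte markers higher in BAFF tumour libraries (adjusted p = 0.887 for each with an estimated correlation, and 0.231 and 0.1403 with an estimated correlation after RLE), and the macrophage call was lost without control tumour 1 (0.0773). The median of the 16 tested macrophage genes minus that of all tested genes was -0.418 on the deposited scale (SD of members 0.4182) and -0.45 after RLE. Each was over 2 SE from 0, but that SE is over members. Members move together (estimated correlation 0.783), so it leaves out the spread between libraries. After RLE the mean log2 of the list was 7.23 to 7.28 in BAFF tumour libraries and 7.60 to 7.88 in controls. Within this limit the difference argues against library scale as the whole cause, although the number passing as lower depended on the scaling (0, and 8 after RLE). For the 12 Ly6C-high genes this difference was 0.5638 (SD of members 0.4125) and 0.53 after RLE. It argues against library scale in the same way and with the same limit (estimated correlation 0.598). A smaller share of macrophages in the sorted cells cannot be told apart from lower transcription in monocytes: 8 markers passed as lower and 1 as higher after RLE, and monocytes transcribe several of these markers. An effect of BAFF on monocyte maturation may equally be the source, and it was not tested.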
